A study of Mus musculus with 8 samples.

How the data were processed

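The series holds 8 libraries of total RNA from mouse kidney, extracted with Trizol from animals aged 8 to 10 weeks. The labels place 3 libraries in the control group, 2 in a group called acute-chronic (AC) and 3 in a group with unilateral ureteral obstruction (UUO). The design text of the series speaks of ischaemia/reperfusion and obstruction, with kidneys taken at day 5, and of sham-operated animals as controls; the sample titles call the controls wild type. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be technical.

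The deposited tables list 6315 circular RNAs (circRNAs), closed RNA loops named by their circBase identifiers, each with a source transcript and, for all but 32, a host gene. Per the file headers they are not genes, and the level of the linear host transcripts is not analysed here. The first table holds whole-number counts per circRNA and library, deposited without normalization. The second is a signal table in which, as the values show, the authors divided each count by 1 constant per library, between 8718 and 11941; multiplied back, 100% of the values were whole within 0.01. The meaning of that constant is not given in the sources used here. Per the submitters' processing notes, HISAT2, StringTie and build mm9 were used, with no role or version given. The caller of circular junctions, its minimum of reads and the annotation release are not given in the sources used here, nor is how a read shared by circRNAs of 1 host was counted. The reference annotation at hand was of another build, so no coordinates, exons or strands are printed. It served only to look up source transcripts, of which 91.2% matched, and to restore the symbols of 10 rows in which the gene name had become a number.

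Counts were tested as deposited with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with all 8 libraries in 1 fit of 3 groups and TMM factors. The default filter (a count of at least 10 in enough libraries, scaled to library size, and a total of at least 15) left 1471 circRNAs of 1016 host genes. These were 23.3% of the rows and held between 82.5% and 84.8% of the counts of each library. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 0.413. The design had been fixed for genes before the data were examined; the same test was run on circRNAs instead. CPM values are circRNA counts scaled to the totals left in each library after the filter, with TMM factors, in the usual CPM unit, given as mean ± SD. Standard errors of log2 fold changes were the absolute fold change over the square root of F. Where a group had 0 counts throughout, a lower bound was computed against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio of group sums is given with an exact binomial 95% interval. Intervals cover counting error only. Bounds cover counting error of the group at 0 only, and take the mean of the other group as it stands. They do not allow for the excess of 0 counts described below, so "at least" refers to counting error alone.

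CircRNAs were named by a rule fixed before the data were examined: for each comparison the 5 largest increases and 5 largest decreases among those past the threshold, with a mean log2 CPM of at least 3 and no overlap between the libraries of both groups, and 25 kidney genes in any case. Of these 25, 1 (Lrp2) had a listed circRNA. The CPM limit had been set for genes. Here a count of 3 was worth at least 56.6 CPM, so that limit was no real screen for abundance. All other names were chosen after their values had been seen. The 54 gene lists fixed in advance could not be tested as sets, because none had 4 tested host genes; the highest number was 3, and 18 lists had any tested member. In their place 12 classes of host genes were compiled after the data had been examined. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 12 classes. Of the 12, 2 were unions of the fixed lists, formed after the fold changes of their members had been seen, so they are not independent evidence of a direction. The other classes were also compiled with the data known, so their tests are not independent evidence either.

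On simulated counts with the real means, dispersions and library sizes, 200 circRNAs were changed in each of 10 runs. In UUO against control, over 1381 circRNAs on average, the test recovered 13.9% of 2-fold and 58.9% of 4-fold changes, and 3.01% of its calls were false. In AC against control, over 1380 circRNAs, it recovered 8.48% of 2-fold and 48.5% of 4-fold changes, with 4.32% false calls. The data held more 0 counts in libraries whose group was otherwise well covered than the fitted model gave (54 against at most 16 in 100 simulations). These rates may therefore not carry over to the real calls. In UUO against control, a simulated log2 shift of -0.5 of the metabolic class, about the size of the observed median, was called in 10 of 10 runs, with 0 calls in 100 tests of other classes. The union of the fixed tubule and metabolism lists was left out of these other classes. Smaller shifts and the AC comparison were not simulated for classes. Each circRNA was drawn independently, so these runs do not show the error rate where members of a class are correlated.

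Alternatives listed before the data were examined were DESeq2 1.42.0, limma-voom, RLE factors, library totals without TMM, scaling without the 50 most abundant circRNAs, no filter, a filter of 50 counts in 3 libraries, fits on only the groups compared, the replicate number as a block, each library left out, limma-trend on the deposited values with pseudocounts of 1 and 0.1, an adjusted p of 0.01 and a test against a 2-fold change. Chosen after seeing the data were the constant between both deposited tables as library size, a pseudocount of 1e-04, and counts summed per host gene. Figures were drawn with matplotlib 3.10.9.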

Results

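CircRNA counts were compared between 3 control, 2 AC and 3 UUO kidney libraries. Total counts were 43971, 65145 and 57566 in control replicates 1 to 3, 49147 and 40865 in AC replicates 1 and 2, and 46899, 50985 and 57754 in UUO replicates 1 to 3. Between 3396 and 3811 circRNAs had a count above 0 in a library. The median circRNA had 14 counts in all 8 libraries together, and a count of 3 was worth between 56.6 and 87.5 CPM. The number of circRNAs above 0 was 3584 ± 205 (SD, n = 3) in control, 3434 ± 53.03 (SD, n = 2) in AC and 3580 ± 117 (SD, n = 3) in UUO. The summed deposited signal was 5.94 ± 1.41 (SD, n = 3) in control, 4.60 ± 0.304 (SD, n = 2) in AC and 4.86 ± 0.228 (SD, n = 3) in UUO. A two-sided exact permutation test of that sum gave p = 0.3 for UUO against control and p = 0.3 for AC against control, where the smallest p the design allows is 0.1. Replicates of each group differed by more than counting noise, with a chi-square per degree of freedom between 3.04 and 5.34, so no library was counted as a duplicate. The first principal component held 25.6% of the variance, with the 3 control libraries at -15.27 or below and the 5 injured libraries at 7.54 or above.

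The comparison of UUO with control asks which circRNAs differ in the kidney 5 days after ureteral obstruction. The circRNA of Dcdc2a, a doublecortin-domain gene linked to cilia (mmu_circ_0004549), was 35.3-fold higher, from 97.0 ± 31.3 CPM (SD, n = 3) in control to 3423 ± 218 CPM (SD, n = 3) in UUO. Its log2 fold change was 5.14 with a standard error of 0.32 and an edgeR adjusted p of 2.90e-08. CircRNAs of Nrg1, an ERBB receptor ligand (mmu_circ_0014776), Osmr, the oncostatin M receptor (mmu_circ_0005739), and Espl1, the protease separase (mmu_circ_0000652), had 0 counts in the 3 controls. Allowing for counting error alone, they were at least 29.6-fold, 15.3-fold and 13.2-fold higher in UUO, with adjusted p of 0.0118, 0.0134 and 0.0178. With 1 UUO library left out, the lowest of these bounds were 22.3-fold, 14.1-fold and 11.1-fold. The Nav3 circRNA (mmu_circ_0000211) had 1 count in control and 45 in UUO, a ratio of 48.2 with an interval from 8.21 to 1944 (adjusted p = 0.0173). With each of the 8 libraries left out in turn, the Dcdc2a call held in 8 settings, Nrg1 in 7, Nav3 in 6, Osmr in 5 and Espl1 in 4. Of these 5, limma-voom called Dcdc2a alone, with adjusted p from 0.0681 to 0.167 for the others.

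Among decreases, the circRNA of Spast, a microtubule-severing ATPase (mmu_circ_0006994), had 4, 27 and 10 counts in control and 0 in the 3 UUO libraries, at least 11.9-fold lower (adjusted p = 0.0161). Without control replicate 2 the bound was 6.78-fold and the adjusted p 0.0744. The Frmd4b circRNA (mmu_circ_0013632) had 82 counts in control and 3 in UUO, a ratio of 25.5 with an interval from 8.44 to 126 (adjusted p = 0.00818). All 3 UUO counts were in UUO replicate 3, and the control libraries had 11, 45 and 26. The circRNA of Cpeb3, a regulator of translation (mmu_circ_0007737), was 6.75-fold lower (log2 fold change -2.75, SE 0.43, adjusted p = 0.00230), from 2376 ± 293 CPM (SD, n = 3) to 352 ± 174 CPM (SD, n = 3). A pair of circRNAs of Klhl3, an adaptor of the WNK kinase pathway in the distal nephron, were 5.22-fold lower (mmu_circ_0004688, adjusted p = 0.0132) and 3.76-fold lower (mmu_circ_0004687, adjusted p = 0.0419). Of 8 settings without 1 library, the Cpeb3 call held in 8, Frmd4b in 7, Spast in 5 and Klhl3 in 5 and 2. In limma-voom the Spast, Frmd4b and mmu_circ_0004687 circRNAs missed the threshold (adjusted p = 0.154, 0.152 and 0.0806). The Lrp2 circRNA of the proximal tubule receptor megalin (mmu_circ_0010128) had a log2 fold change of -0.97 with an SE of 0.52 and did not pass (adjusted p = 0.401).

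In all, 64 of 1471 circRNAs passed the threshold, 42 higher and 22 lower in UUO, and 34 and 17 of them by at least 2-fold. An unadjusted p under 0.05 was found for 228, against 73.6 expected by chance. Of all tested circRNAs, 24.3% had no overlap between the libraries of both groups, where chance gives 10%. With the constant between both deposited tables as library size, the median of all circRNAs moved from 0.016 to -0.26 on the log2 scale, and 37 passed, 11 higher and 26 lower, with no called circRNA changing sign. The count fell to 40 without control replicate 2, 25 without control replicate 3, and 26, 10 and 15 without UUO replicates 1, 2 and 3. With each of the 8 libraries left out in turn, 7 of the 64 passed every time: Dcdc2a, Samd4, Cryl1, Cpeb3, Tns3 (mmu_circ_0000233), Psd3 (mmu_circ_0001683) and Epb4.1l2 (mmu_circ_0002128). Each other call was lost in at least 1 of these settings, the mmu_circ_0004688 circRNA of Klhl3 without any 1 UUO library (adjusted p = 0.0632, 0.0620 and 0.0768).

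**Figure D1:**
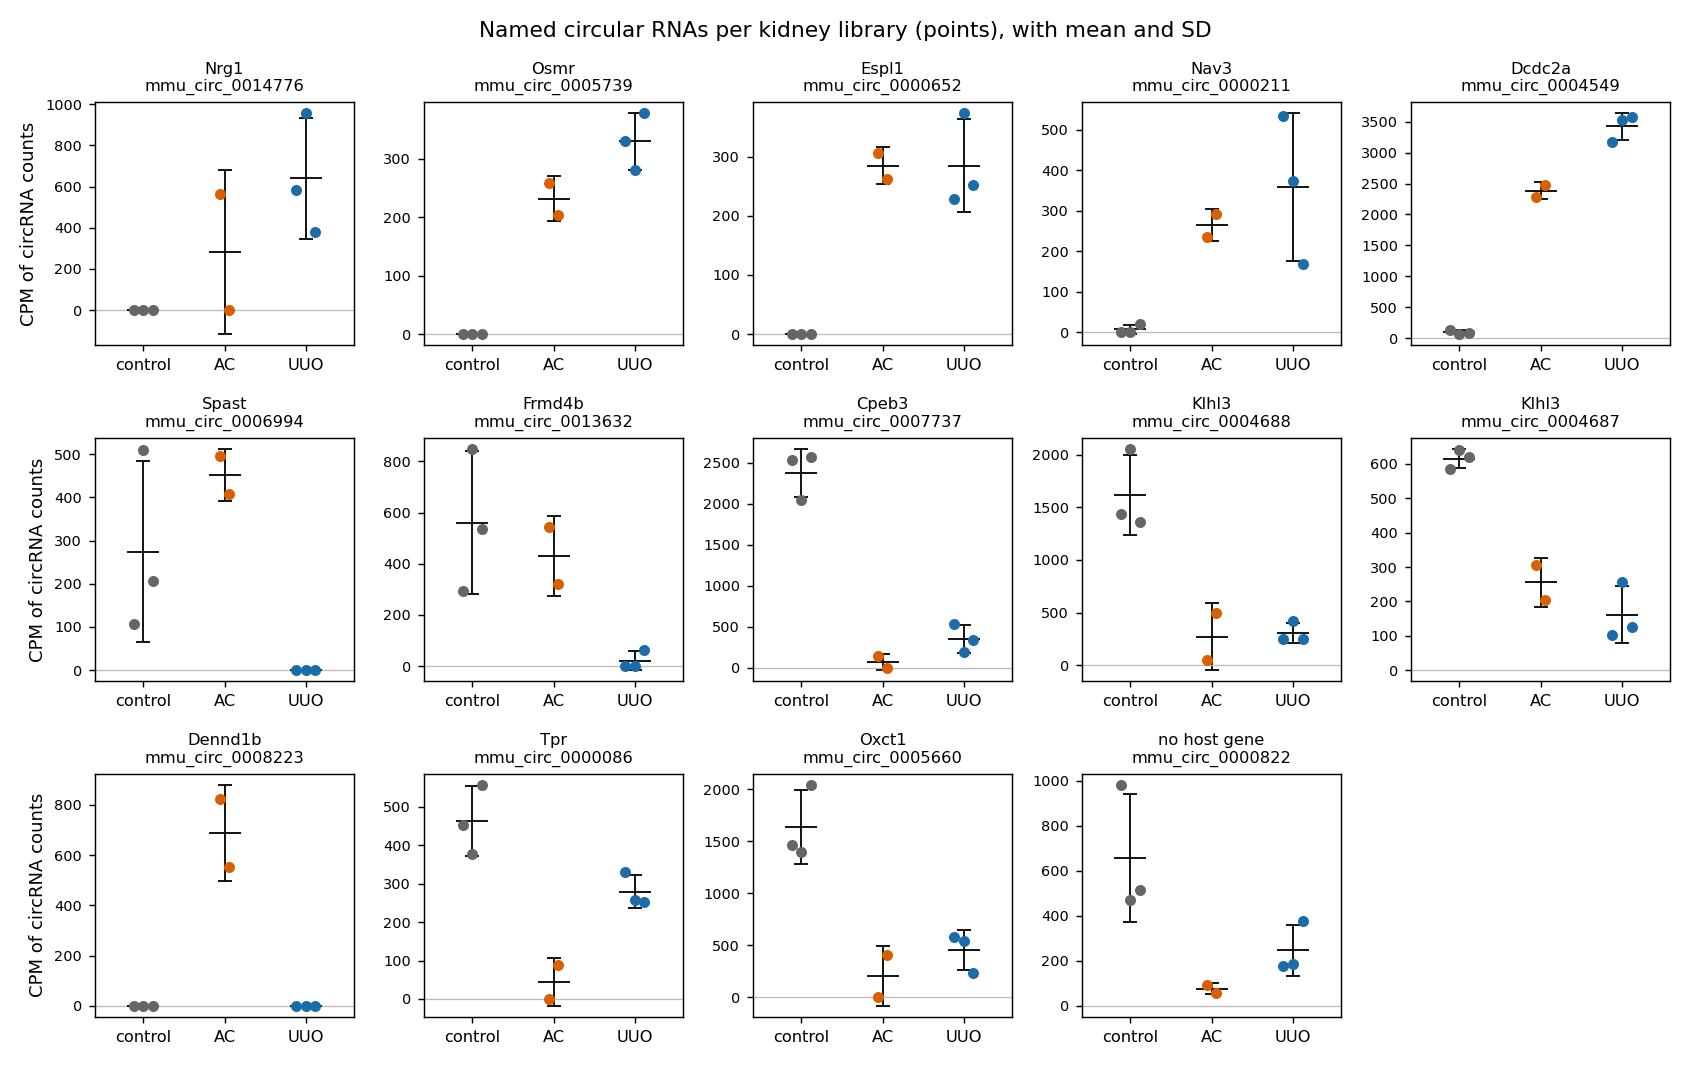
CPM of the 14 circRNAs with the largest increases and decreases by the rule fixed in advance (Lrp2, named in any case, is not drawn), in each of the 8 kidney libraries (points, coloured by group: control, AC, UUO), with the group mean and SD as bars. Each panel has its own linear axis; the Dcdc2a circRNA is at 97.0 CPM in control, 2382 in AC and 3423 in UUO on average.

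CircRNAs of metabolic and mitochondrial host genes were lower as a class in UUO. The class was compiled after the data had been examined, so its test is not independent evidence of a direction. Of 79 circRNAs from 63 such hosts, 53 had a negative log2 fold change, with a median of -0.51. Of these circRNAs 6 passed as lower and 1 as higher. The class was lower than other circRNAs (camera adjusted p = 4.57e-05, and 0.0402 with an estimated correlation). With the constant between both deposited tables as library size, the class median was -0.80, with 59 negative values. The median of all circRNAs was then -0.26. Lower members included Cryl1, an L-gulonate dehydrogenase (mmu_circ_0000543, 3.18-fold lower, log2 SE 0.21, adjusted p = 1.50e-04), and Ogdh, a subunit of the oxoglutarate dehydrogenase of the citric acid cycle (mmu_circ_0000231, 2.02-fold lower, log2 SE 0.18, adjusted p = 0.00707). Oxct1, an enzyme of ketone body use (mmu_circ_0000571), was 2.59-fold lower. The higher member was Smox, spermine oxidase (mmu_circ_0001068, 3.33-fold higher). Of 8 settings without 1 library, the Cryl1 call held in 8, Ogdh in 7, Oxct1 in 5 and Smox in 3.

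The union of fixed tubule and metabolism lists held 17 circRNAs of 11 hosts, all 17 with a negative log2 fold change and 6 past the threshold. Its camera adjusted p was 2.84e-08, and the adjusted p was 0.0563 with an estimated correlation. The union overlaps with the metabolic class, for example in the Ogdh circRNA, so their results are not separate. Besides Ogdh and Klhl3, Slc7a8, an amino acid transporter (mmu_circ_0000539), was 2.29-fold lower and 2 circRNAs of Bckdhb, of branched-chain amino acid breakdown, were 2.67-fold (mmu_circ_0015952) and 1.87-fold (mmu_circ_0001822) lower; these 3 calls held in 4, 4 and 5 of 8 settings without 1 library. The union of fixed injury, inflammation and fibrosis lists held 14 circRNAs of 11 hosts, 12 with a positive log2 fold change and 3 past the threshold. Despite its name, 0 of the 14 came from the lists of tubular injury, matrix and fibrosis, fibroblasts, immune cells, chemokines, complement or interferon. They came from the failed-repair (2), TGF-beta (6), cell cycle (1), p53 (2), Wnt, Notch and Hippo (2) and epithelial-mesenchymal (1) lists; Nfkb1, of the first, is also on the NF-kappaB list. Its camera adjusted p was 0.01004, and the adjusted p was 0.180 with an estimated correlation and 0.0843 without control replicate 1. The 3 were Dcdc2a, Nfkb1, a subunit of NF-kappaB (mmu_circ_0010477, 1.996-fold higher), and Bub1b, of the spindle checkpoint (mmu_circ_0001058, 2.69-fold higher). The Nfkb1 call (adjusted p = 0.0433) held in 0 of 8 settings without 1 library and Bub1b in 2. The other 9 classes had adjusted p between 0.0868 and 0.802; the lowest was that of 14 circRNAs of the Hippo pathway.

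Within the lists fixed in advance, both tested circRNAs of the failed-repair proximal tubule list (1 each of Dcdc2a and Nfkb1) were higher in UUO and in AC, adjusted over the list alone and over all tested circRNAs. Over all tested circRNAs, leaving out any 1 library ended the Nfkb1 call in UUO (adjusted p from 0.0514 to 0.162), and in AC the call held in 4 of 8 such settings. The 6 tested circRNAs of the TGF-beta list came from Smad4, Ltbp1 and Tgfbr2, and 0 passed in UUO or in AC. The 4 tested circRNAs of the amino acid and NAD list were lower in 2 cases in UUO over all tested, and 2 when adjusted over the list alone. In AC these counts were 1 over all tested and 4 when adjusted over the list alone.

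The comparison of AC with control asks the same of the libraries labelled acute-chronic, also taken at day 5. The Dcdc2a circRNA was 24.5-fold higher, at 2382 ± 137 CPM (SD, n = 2), with a log2 fold change of 4.62, an SE of 0.34 and an adjusted p of 3.52e-07. The circRNA of Dennd1b, a Rab exchange factor (mmu_circ_0008223), had 0 counts in control and in UUO and 689 ± 191 CPM (SD, n = 2) in AC. It was at least 31.9-fold higher in AC than in control (adjusted p = 0.0214). The other 3 tested Dennd1b circRNAs had negative log2 fold changes in AC, down to -0.33, and did not pass. The Espl1 and Osmr circRNAs were at least 13.2-fold and 10.7-fold higher (adjusted p = 0.0220 and 0.0228). Without AC replicate 1 these bounds were 12.2-fold and 9.46-fold, and that of Dennd1b was 25.7-fold. The Nav3 circRNA had 20 counts in AC against 1 in control, a ratio of 36.2 with an interval from 5.79 to 1501 (adjusted p = 0.0339). With each of the 8 libraries left out in turn, the Dcdc2a call held in 8 settings, Dennd1b in 5, Espl1 and Osmr in 3 and Nav3 in 1. In limma-voom Espl1, Osmr and Nav3 missed the threshold (adjusted p = 0.151, 0.196 and 0.294).

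The Cpeb3 circRNA was 29.8-fold lower in AC (log2 fold change -4.90, SE 0.64, adjusted p = 3.90e-04), with counts of 6 and 0 in the AC libraries against 95, 108 and 124 in control. Without AC replicate 2 it was 16.8-fold lower (adjusted p = 0.00125), and without AC replicate 1 the group was at 0 counts. The circRNA of Tpr, a nuclear pore protein (mmu_circ_0000086), had 64 counts in control and 3 in AC, a ratio of 11.8 with an interval from 3.85 to 58.6 (adjusted p = 0.0415). All 3 AC counts were in AC replicate 2; without AC replicate 1 its fitted decrease was 5.30-fold (adjusted p = 0.271). An Oxct1 circRNA (mmu_circ_0005660) was 8.46-fold lower (adjusted p = 0.0228), with counts of 0 and 14 in AC. It was 4.11-fold lower without AC replicate 1 (adjusted p = 0.106), and the DESeq2 adjusted p was 0.0738. A circRNA with no host gene (mmu_circ_0000822) had a log2 fold change of -3.03 (SE 0.70, adjusted p = 0.0220), and the Klhl3 circRNA mmu_circ_0004688 was 6.22-fold lower (adjusted p = 0.0220). The Klhl3 circRNA had uneven counts of 2 and 17 in AC, was 3.37-fold lower without AC replicate 1 (adjusted p = 0.134) and 33.1-fold lower without AC replicate 2, and also missed the threshold without control replicate 3 (adjusted p = 0.0558). Of 8 settings without 1 library, the Cpeb3 call held in 8, Klhl3 in 6, Oxct1 in 5, mmu_circ_0000822 in 4 and Tpr in 1. In limma-voom Klhl3 alone of these 5 passed, with adjusted p of 0.0958 for Cpeb3 and from 0.122 to 0.369 for the others. The Lrp2 circRNA had a log2 fold change of -0.70 with an SE of 0.59 and did not pass (adjusted p = 0.676).

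In all, 49 circRNAs passed, 28 higher and 21 lower in AC, and 25 and 20 of them by at least 2-fold. An unadjusted p under 0.05 was found for 207, against 73.6 expected. Of all tested circRNAs, 30.7% had no overlap between the libraries of both groups, where chance gives 20%. With the constant between both deposited tables as library size, the median of all circRNAs moved from -0.015 to -0.34, and 29 passed, 7 higher and 22 lower, with no called circRNA changing sign. The count was 14 in a fit on AC and control alone, 11 without control replicate 3, 13 and 15 without AC replicates 1 and 2, where the lone AC library was assumed to vary like the other groups, and 32 without UUO replicate 2. With each of the 8 libraries left out in turn, 6 of the 49 passed every time: Dcdc2a, Samd4, Cryl1, Cpeb3, Sh2d4b and Arhgap32 (mmu_circ_0001764).

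Among the metabolic and mitochondrial hosts, 55 of 79 circRNAs had a negative log2 fold change in AC, with a median of -0.51. As lower, 7 passed, and 2 passed as higher, from Smox (4.25-fold) and H6pd (mmu_circ_0011434, 2.22-fold). The camera adjusted p was 2.02e-04, and the adjusted p was 0.0712 with an estimated correlation. With the constant between both deposited tables as library size, the class median was -0.86, with 62 negative values. The median of all circRNAs was then -0.34. The Cryl1 circRNA was 5.98-fold lower (log2 SE 0.26, adjusted p = 1.48e-05) and that of Papss1, which makes the sulfate donor PAPS (mmu_circ_0001170), 5.87-fold lower (adjusted p = 0.0228). The Papss1 circRNA had uneven counts of 11 and 1 in AC, was 3.51-fold lower without AC replicate 2 (adjusted p = 0.187) and 29.1-fold lower without AC replicate 1, and passed in 3 of 8 settings that left out 1 library. In the union of fixed tubule and metabolism lists, 15 of 17 circRNAs had a negative value and 4 passed as lower. Among the 4 was a circRNA of Slc4a4, a bicarbonate transporter (mmu_circ_0012844), 4.05-fold lower, with counts of 10 and 4 in AC. It was 6.37-fold lower without AC replicate 1. The other tested Slc4a4 circRNA had a log2 fold change of 0.087 in AC. The Slc4a4 and H6pd calls held in 0 of 8 settings without 1 library, and Smox in 5. The union had a camera adjusted p of 1.21e-05, and of 0.0835 with an estimated correlation.

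The injury, inflammation and fibrosis union, with the same limited membership, had 11 of 14 circRNAs with a positive value in AC and 2 past the threshold, Dcdc2a and Nfkb1 (2.48-fold higher). Its adjusted p was 0.0148, and the adjusted p was 0.123 with an estimated correlation and 0.109 without control replicate 1. Of 14 Hippo pathway circRNAs, 10 had a positive value and 2 passed, from Ptpn14 (mmu_circ_0000130, 3.84-fold higher) and Trip6 (mmu_circ_0012217, 2.16-fold higher). The class had an adjusted p of 0.0148, and 0.0835 with an estimated correlation. Of 54 circRNAs in the compiled class of receptor tyrosine kinase, MAP kinase and PI3 kinase signalling, 38 had a positive value and 4 passed. Among the 4 were Osmr, the oncostatin M receptor, and Nrg1, which had 24 and 0 counts in the AC libraries. The class had a camera adjusted p of 0.0371, and 0.0835 with an estimated correlation. Of 65 circRNAs of adhesion, junction and actin genes, 38 had a positive value and 3 passed, from Tns3, Nedd9 and Cd2ap. Their class had an adjusted p of 0.0473, and 0.0835 with an estimated correlation, and its median changed from 0.17 to -0.19 under scaling by the deposited constant. Under that scaling the median of the Hippo class went from 0.485 to 0.152, with 9 of 14 positive. That of the kinase signalling class went from 0.345 to 0.0305, with 31 of 54 positive. The median of all circRNAs moved from -0.015 to -0.34, so a shift common to all circRNAs is part of these changes. No class was tested under that scaling. These last 3 classes passed in 5, 3 and 3 of 8 settings that left out 1 library. Of the calls named in them, Ptpn14 and Cd2ap held in 5 such settings, Trip6 in 4, Osmr and Tns3 in 3, and Nrg1 and Nedd9 in 1. The other 6 classes had adjusted p between 0.277 and 0.666. All 12 classes were compiled after the data had been examined. Calls already seen could enter them, so no adjusted p of a class is independent evidence.

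**Figure D2:**
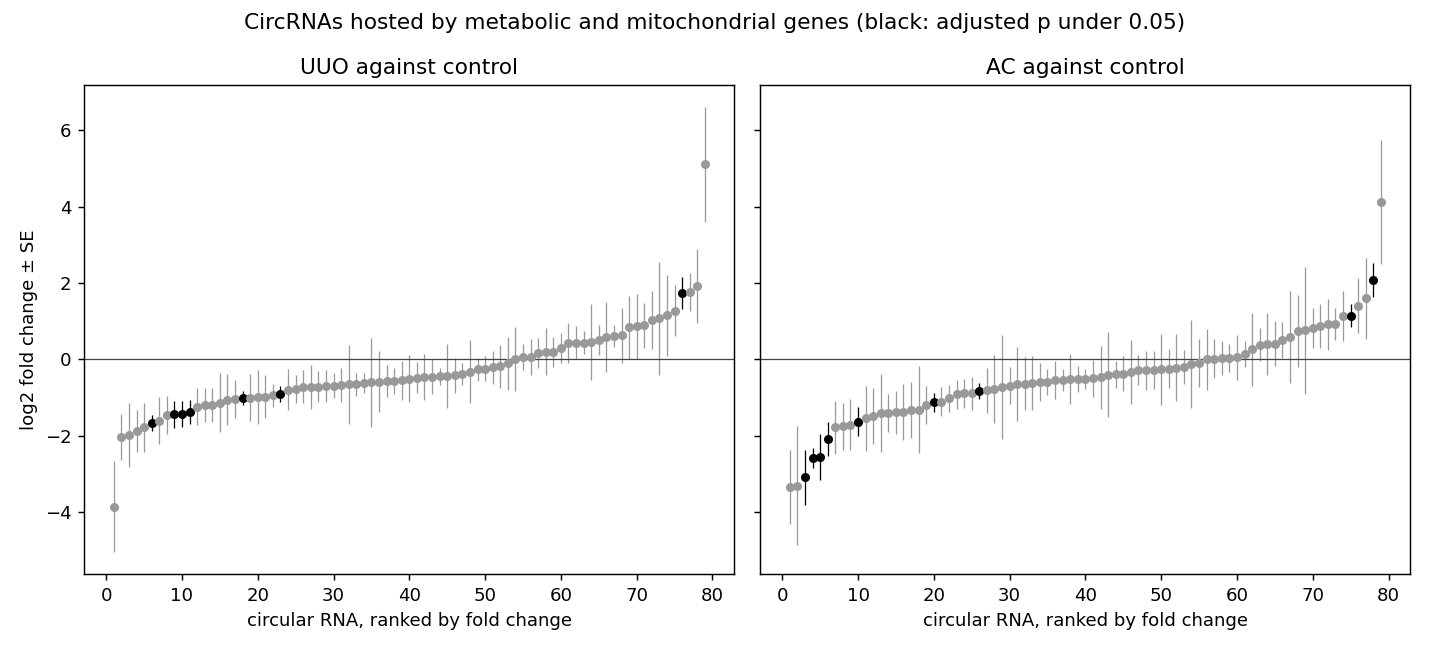
Log2 fold changes with their standard errors for the 79 circRNAs of metabolic and mitochondrial host genes, ranked within each comparison (left, UUO against control; right, AC against control). Black points have an adjusted p under 0.05; 53 values lie below 0 in UUO and 55 in AC.

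The direct comparison of UUO with AC passed 0 circRNAs in edgeR, with a smallest adjusted p of 0.133. An unadjusted p under 0.05 was found for 82 circRNAs, against 73.6 expected. No overlap between the libraries of both groups was found for 24.3% of tested circRNAs, where chance gives 20%. Recovery of known changes was not simulated for this comparison, so 0 calls do not show that both groups are alike. DESeq2 called 1, the Spast circRNA mmu_circ_0006994, lower in UUO (log2 fold change -6.77, adjusted p = 0.0120), and limma-voom called 0. The Spast circRNA had 21 and 14 counts in AC and 0 in each UUO library. The Dennd1b circRNA, at 0 in UUO, had an edgeR adjusted p of 0.158 between UUO and AC, as did the Frmd4b circRNA. The Lrp2 circRNA had a log2 fold change of -0.26 (adjusted p = 0.991), and 0 of 12 host gene classes passed, with adjusted p between 0.735 and 0.977.

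The 2 comparisons with control overlapped in 33 circRNAs, 22 higher in both and 11 lower in both, with 0 in opposite directions. Shared increases included Dcdc2a, Samd4 (mmu_circ_0000529, 11.2-fold in UUO and 9.60-fold in AC), Sh2d4b (mmu_circ_0005234, 7.28-fold and 10.2-fold; in AC its log2 fold change was 3.36, and 3.95 without control replicate 2) and 2 circRNAs of Psd3, an Arf exchange factor (mmu_circ_0001683 and mmu_circ_0001682). Shared decreases included Cryl1, Cpeb3, Ogdh, Lactb2 and 2 circRNAs of Arhgap10 (mmu_circ_0001692, 1.96-fold and 2.27-fold lower, and mmu_circ_0001691). The Ogdh call held in 7 of 8 settings without 1 library in UUO and in 1 in AC. Independent lists of these sizes would share 0.799 higher and 0.314 lower circRNAs, and 100 simulations of unchanged groups against the same controls shared at most 1. Unchanged groups have hardly any calls to share, so that number does not measure overlap among real calls. Across 1471 circRNAs, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.62 and a Spearman correlation of 0.63, against a mean of 0.43 and 0.41 in the simulations. The covariance was 0.828 against a simulated mean of 0.228, a difference of 0.599. With 3 controls, the controls cannot be split into parts of at least 2 libraries each, and part of the excess may come from the shared controls. The correlation was 0.43 without AC replicate 1 and 0.34 without AC replicate 2, where the filter kept more circRNAs of low count. Over the circRNAs of the full fit it was 0.434 and 0.386, against at most 0.374 and 0.395 in 100 simulations of each setting, so without AC replicate 2 it lay within the simulated range. The Spearman correlation was 0.528 and 0.463 in these settings, above the simulated highest of 0.375 and 0.384. Shared calls numbered 9 without control replicate 3, 7 and 11 without AC replicates 1 and 2, and 13, 9 and 9 without UUO replicates 1, 2 and 3.

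**Figure D3:**
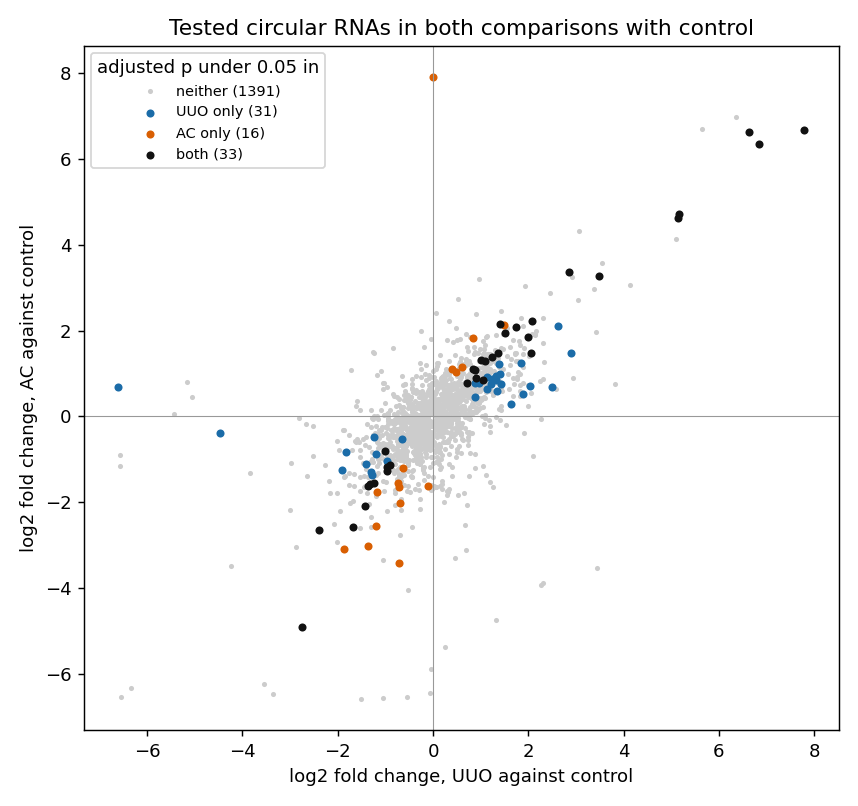
Fitted log2 fold changes of the 1471 tested circRNAs in UUO against control (horizontal) and AC against control (vertical). Black points (33) passed in both comparisons, blue (31) in UUO and orange (16) in AC; a value that involves a group at 0 counts throughout depends on the prior count.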

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

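Depth limits the named circRNAs with low counts, since a count of 3 is worth at least 56.6 CPM. Groups of 2 or 3 libraries leave little room to drop one. Alternatives chosen after seeing the data are the scaling constant, the pseudocount of 1e-04, counts per host gene and all tests of host gene classes. Causes were not tested unless stated. In UUO against control, the 64 calls became 97 with DESeq2, 73 with limma-voom, 37 with the constant as library size, 41 with a pseudocount of 1e-04, 20 and 18 with pseudocounts of 1 and 0.1, 12 at an adjusted p under 0.01 and 10 against a 2-fold change. In AC against control, the 49 became 70 with DESeq2, 39 with limma-voom, 14 with the groups compared alone (fewer libraries to estimate the spread), 29 with the constant, 5 and 4 with pseudocounts of 1 and 0.1, 9 at the stricter p and 5 against a 2-fold change. Both pseudocounts lie near or above the largest deposited value of 0.107, and a filter at a mean of 1 left 0 rows, so it gave no value. In UUO against AC, 0 became 1 with DESeq2, 4 without a filter, 1 with the groups compared alone and 1 with either large pseudocount. The correlation of log2 fold changes was 0.46 with DESeq2 and 0.46 without a filter, both over more circRNAs of low count. Classes past the threshold went from 3 to 1 with an estimated correlation and 6 with fry in UUO, and from 6 to 0 with an estimated correlation and 7 with fry in AC; fry tests a class against no change, not against other circRNAs. Under limma-voom 14 of the 20 calls named by the rule were lost, 7 in each comparison with control. The fixed lists allowed no set test under any setting.

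Leaving out 1 library at a time gave 10 to 75 calls in UUO against control, 11 to 38 in AC against control and 0 to 1 in UUO against AC. The correlation ranged from 0.34 to 0.69 and the shared calls from 7 to 25. Classes ranged from 2 to 4 in UUO, 3 to 6 in AC and 0 to 0 between them. The metabolic class passed in 8 of 8 such settings in both comparisons with control, and with an estimated correlation in UUO (adjusted p = 0.0402) but not in AC (0.0712). The Dcdc2a and Cpeb3 circRNAs passed under 22 of 22 alternatives in UUO (highest adjusted p 8.44e-04 and 0.0381), and under 20 and 21 of 22 in AC. The Lrp2 log2 fold change between UUO and AC (mmu_circ_0010128), not past the threshold, ranged from -0.52 without UUO replicate 1 to 0.050 without UUO replicate 3, where it changed sign. No other log2 fold change of a circRNA named by the rule changed sign under these alternatives.

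Samples with the same replicate number did not deviate together: correlations of their deviations ran from -0.11 to 0.04. With the replicate block, 12 circRNAs passed in UUO against control, 5 in AC against control and 0 between them, and 4 were shared. The correlations gave no sign that the numbers pair the samples. Deviations taken within such small groups cannot exclude pairing.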

Other observations

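The tests without 1 AC library, of counts summed per host, of the 0 counts by a detection step, of Uty and of circRNAs of 1 host were chosen after the results had been seen; the correlation, the 64 calls and some of the 0 counts had been seen before their simulations or regroupings were run.

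Some host genes contributed several circRNAs that changed in 1 direction. All 7 tested circRNAs of Arhgap10 had negative log2 fold changes in UUO and in AC, from -1.88 to -0.16 and from -1.30 to -0.31, and 3 and 2 of them passed. All 5 circRNAs of Arhgap32 were negative in AC and 4 passed, from 2.31-fold lower (mmu_circ_0001765) to 3.36-fold lower (mmu_circ_0015520); 0 of the 5 passed in UUO, where all 5 were also negative, and none of these 4 passed between UUO and AC. Summed per host, Arhgap32 counts were lower in UUO (log2 fold change -0.70, adjusted p = 0.00911) and in AC (-1.59, adjusted p = 1.45e-05). Some circRNAs passed in UUO and not in AC, such as Epb4.1l2 (mmu_circ_0002128, 7.43-fold higher), Svep1 (mmu_circ_0011707, 3.11-fold) and Nfix (mmu_circ_0001704, 1.85-fold), which held in 8, 2 and 5 of 8 settings without 1 library, and between UUO and AC 0 circRNAs passed.

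A hypothesis is that circRNA changes follow the host gene. Over 775 pairs of circRNAs that share 1 of 268 hosts, 62.5% had the same sign in UUO and 59.5% in AC, against 49.9% and 50% with permuted hosts. The mean product of their log2 fold changes was 0.278 in UUO and 0.269 in AC, above the highest of 10000 permutations (0.248 and 0.221; permutation p = 1e-04, the smallest they can give). Between UUO and AC, where 0 circRNAs passed, 54.1% of pairs had the same sign, against 50% with permuted hosts. There the mean product was 0.0677 (permutation p = 0.037). The permutations exchanged host labels and not libraries, so their p does not measure the spread between libraries. Reads shared by circRNAs of 1 host, or variation between libraries common to them, could give the same pattern and were not tested.

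AC and UUO fold changes went together. Shared controls alone gave a covariance of at most 0.292 in 100 simulations, below the observed 0.828. Control replicate 2, which had the highest summed signal, did not account for it either, since without it the covariance was 1.06 against at most 0.462. Without AC replicates 1 and 2 the covariance was 0.849 and 0.796 against at most 0.347 and 0.329. The correlation fell from 0.62 to 0.434 and 0.386 over the same circRNAs, against at most 0.374 and 0.395, so without AC replicate 2 the Pearson value lay within the range of unchanged groups; the Spearman values of 0.528 and 0.463 lay above it (at most 0.375 and 0.384). Controls that vary more than the fitted noise were not simulated, so a part from shared controls stays open. A common response to injury stays open as a hypothesis, as does a difference between sham or wild-type animals and operated ones that is unrelated to either injury.

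Some circRNAs had 0 counts in 1 library while each other library of the group had at least 15. There were 54 such places of 4842, against a mean of 8.75 and at most 16 in 100 simulations from the fitted model, so the excess over these simulations is beyond the fitted noise, while single places may not be. Of the 54, 16 were in AC replicate 2, among them Mllt10 (mmu_circ_0000983) and Arl8b (mmu_circ_0012927). AC has 2 libraries, so there the condition rests on 1 other library and is easier to meet. AC replicate 2 also had the lowest total count (40865), and no simulated number per library was computed. A detection step that turns all low support into 0 was tested first and failed: 0 counts were to outnumber counts of 1 to 4, and the difference was -16. A weaker form was then set with the counts already known, that low counts be fewer than in every simulation; they were 70 against 73 to 120, so a partial step may contribute, on a test that was fitted to the outcome and by a narrow margin.

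The Y-linked gene Uty had 4 listed circRNAs, with summed counts of 26, 0 and 7 in control, 16 and 11 in AC, and 0, 29 and 13 in UUO. At the lowest share of the other 6 libraries, a count of 0 had a negative binomial probability of 0.00667 in control replicate 2 and 0.0187 in UUO replicate 1 at the common dispersion, and of 0.203 and 0.244 at that of the 1 tested Uty circRNA. That last dispersion was estimated from these same libraries with their 0 counts. The probabilities at it therefore cannot decide whether noise gave the 0 counts. Control replicate 2 had the highest total count of the 8 libraries (65145), so low depth does not account for its 0. Noise stays open. Animals of both sexes could also give these 0 counts; with 0 other Y-linked hosts listed, this cannot be told apart from other sources of 0 counts, and the labels used here give no sex.

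Of 10 splits of the 3 control and 3 UUO libraries into groups of 3, 1 gave as many as 64 calls, the real one, and the highest other gave 1; 10 splits are too few for a share under 0.05.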
